A study of Homo sapiens with 6 samples.

How the data were processed

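Poly(A) RNA was sequenced from 6 PANC-1 cultures, 3 with an empty vector (EV) and 3 overexpressing DUSP5 (DUSP5-OE), as paired reads on an Illumina NovaSeq, per the labels' protocols. Groups and replicate numbers were taken from the sample titles and the series' design text. The submitters' processing notes name fastp (version not given), HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build GRCh37, with no roles or order. How the values were normalised is not given in the sources used here.

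The deposited values are a signal of gene read counts divided by 1 size factor per library, as the values themselves show, although the table's own name speaks of FPKM. In each library 100% of the values were whole multiples of 1 step within 0.001 reads, with the same step for every gene, and the size factors were 0.941 to 1.10. Multiplying by these factors recovered totals of 15215332 to 16946918 reads per library. The design, the gene lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined. That design had assumed FPKM. Its test, limma on a log2 scale, was kept as written on the deposited values, and the count tests edgeR and DESeq2 were run on the recovered reads as alternatives chosen after seeing the data. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. A group with 0 reads was given a floor of 3 reads over the group, and ratios with 1 to 3 reads have an exact binomial (Clopper-Pearson) interval at 95%.

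Of the 26492 genes, 25167 were given a symbol from the gene name table or, for 152, from GENCODE 29, and 1325 (5%) had none and are not named. Transcript GC content and length came from the longest transcript in GENCODE 29, which is of another build than the authors', so no coordinates are given. They covered 95.9% of the tested genes.

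Genes with a mean value of at least 1 over the 6 libraries (21696) were tested with limma 3.58.1 in R 4.3.3 on log2(value + 0.5), with moderated variances (trend and robust) and Benjamini-Hochberg adjustment at 0.05. Of the 31 gene lists, the 30 with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the lists. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

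Named genes followed a fixed rule: DUSP5 and SCD; the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 and groups that did not overlap; up to 4 called members per list, with the most abundant member where fewer than 2 were called; and a set of core lipid, ferroptosis and ERK genes. ACACA, of that set, was not matched to a tested gene, and some genes that the rule takes are not reported here. AIFM2, ACSL3, DGAT2, UGDH, NQO1, PTPRC, LYZ, CD14, HOXC10 and PAX2 are list members named in addition, after their values were seen.

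On simulated counts for this comparison, with 100 genes changed 2-fold and 100 changed 4-fold, limma (21420 genes tested) recovered 57% of genes changed 2-fold and 93% of those changed 4-fold, with 11.8% false calls among 170. edgeR 4.0.16 (14906 genes) recovered 58% and 94% with 6.2% false calls among 162, and DESeq2 1.42.0 (25961 genes) 65% and 94% with 14.1% among 185. In this simulation each share of false calls exceeded the adjusted p threshold of 0.05. On data simulated with a GC trend in 1 EV library (20552 genes), removing the trend took its slope from 0.0494 to 2e-04 and left 92.9% of the genes changed 4-fold recovered.

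The fixed alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5, 3 other scalings, moderation without trend and robust, the replicate number as a block, and leaving out each library. For the lists they were an estimated correlation and fry. A mean of at least 10, edgeR, DESeq2, and removal of each library's trend on GC content or transcript length (a lowess with a span of 0.3) were added after seeing the data. The labels give no batch. Replicate numbers occur in both groups, but the fixed design had no replicate block, so the libraries were not treated as paired. Same-numbered libraries did not deviate together.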

Results

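Transcript levels were measured by poly(A) RNA sequencing in PANC-1, a human cell line derived from a pancreatic ductal adenocarcinoma. The 6 libraries fell into 2 groups of 3: cells carrying an empty vector (EV) and cells made to overexpress DUSP5 (DUSP5-OE), a nuclear phosphatase that inactivates ERK kinases. The EV libraries held 16946918, 16290319 and 15654115 reads assigned to 26492 genes, and the DUSP5-OE libraries 15402536, 15935634 and 15215332. All values below are normalised read counts, in which each library's counts were divided by 1 size factor. The series labels describe the 3 libraries of each group as independent biological replicates. Fold changes are DUSP5-OE against EV on the log2(value + 0.5) scale, which can understate or overstate the change of genes with few reads. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over 21696 genes. The comparison asked how DUSP5 overexpression alters the transcriptome, with the title of the series pointing to ferroptosis, an iron-dependent cell death driven by lipid peroxidation, and to stearoyl-CoA desaturase (gene SCD).

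DUSP5 separated the groups in every library. Its level was 178, 145 and 202 in the EV libraries and 21622, 21489 and 21811 in the DUSP5-OE libraries, or 175 ± 28.5 against 21641 ± 162 (SD, n = 3). The 124-fold rise (log2 fold change 6.96 ± 0.165 SE, limma adjusted p = 1.3e-08) was larger than the spread between replicates, and reads of the introduced and of the endogenous gene were not told apart. SCD, which makes monounsaturated fatty acids from saturated ones, stood at 50125, 52528 and 34908 in EV and at 1534, 1636 and 1744 in DUSP5-OE. That 28.0-fold fall (45854 ± 9555 against 1638 ± 105, SD, n = 3) gave a log2 fold change of -4.79 ± 0.179 SE and a limma adjusted p of 3e-07.

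**Figure D1:**
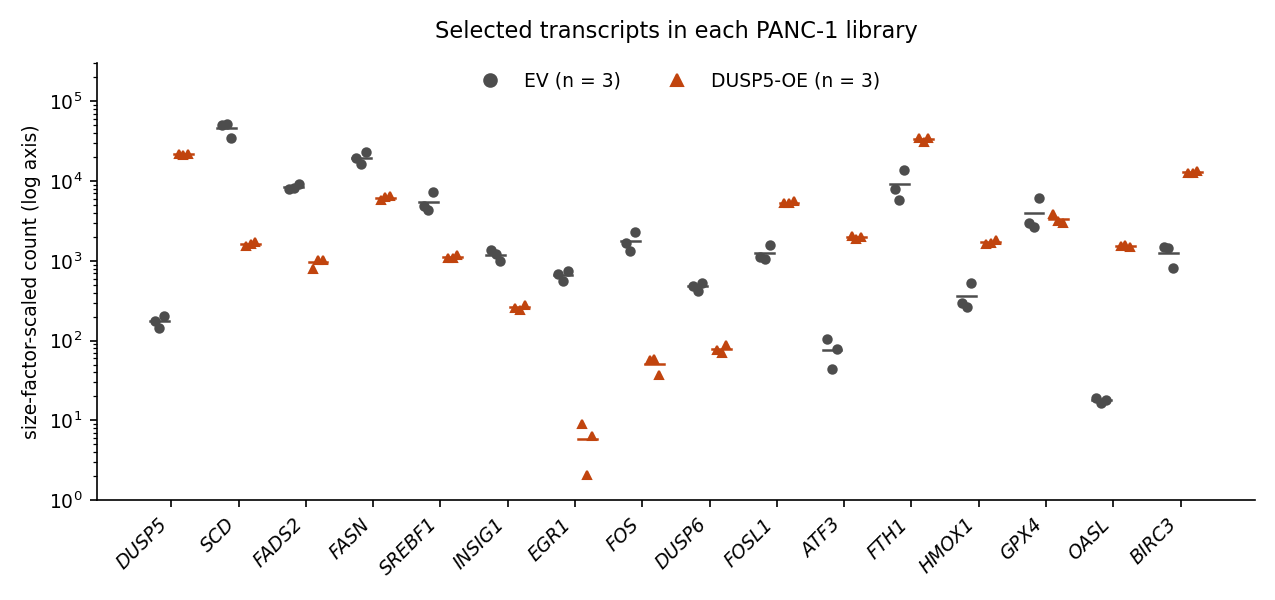
Normalised read counts (log axis) of 16 transcripts in the 3 EV libraries (circles) and the 3 DUSP5-OE libraries (triangles), with a bar at each group mean. SCD lies at 34908 or above in every EV library and at 1744 or below in every DUSP5-OE library, while the values of GPX4 overlap between the groups.

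Interferon genes were among the 10 largest rises, with DUSP5 not counted. RSAD2, which encodes the antiviral enzyme viperin, had 0 reads in all EV libraries and 344 ± 41.3 (SD, n = 3) in DUSP5-OE, at least 363-fold higher against a floor of 3 reads over the EV group. The others were the interferon lambda genes IFNL1 (3.53 ± 4.53 to 548 ± 49.8) and IFNL2 (2.82 ± 2.46 to 214 ± 62.0), NEURL3, the guanylate-binding protein GBP5 (at least 89.2-fold), the NKG2D ligand RAET1L (at least 62.2-fold), KLHDC7B, CMPK2, IFI44 and the cytokine subunit EBI3. KLHDC7B rested on 1 EV read, so its ratio of 223 has an exact binomial counting interval of 39.6 to 8862, and IFNL2 is uncertain because near-identical interferon lambda genes can share reads. The 10 largest falls were led by the transcription factor EGR1, at 664 ± 93.4 in EV and 5.83 ± 3.55 in DUSP5-OE (log2 fold change -6.91 ± 0.438 SE, limma adjusted p = 1.1e-05). Among them were also the glucose transporter SLC2A12 (-5.71), the phosphatase inhibitor PPP1R1B (-5.38), FOS (-5.09), SLITRK6 (-4.99), the cyclooxygenase PTGS1 (-4.98), the deiodinase DIO3 (-4.95), SCD and the peptide receptor RXFP4 (-4.66). The IFNL1 log2 fold change of 7.93 was 6.85 without EV replicate 1 and 8.95 without EV replicate 3, and the IFNL2 log2 fold change of 6.55 was 7.14 and 5.47. The RXFP4 log2 fold change was -5.70 without DUSP5-OE replicate 1 and -3.74 without DUSP5-OE replicate 3, and its call ended with moderation without trend and robust (adjusted p = 0.061).

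Across the transcriptome 1638 genes were higher and 1076 lower in DUSP5-OE at an adjusted p below 0.05 in limma, 955 and 651 of them by at least 2-fold. The groups did not overlap for 7136 genes, 32.9% of those tested, where chance gives 10%. Higher genes were 60.4% of these calls. They were 54.3% with each library rescaled to an equal total, 55.7% with quantile normalization and 54.7% with the GC trend removed. With edgeR's quasi-likelihood test on the recovered reads, which also has its own scaling and tested 14887 genes, they were 50.4% (1433 higher and 1408 lower). EV replicate 3 stood apart from the other EV libraries, and the counts were 4358 and 3591 without it, 979 and 565 without EV replicate 1, and 674 and 458, 571 and 392, and 578 and 404 without DUSP5-OE replicates 1, 2 and 3. Without EV replicate 3 the difference between the groups followed transcript GC content more closely (Spearman's rho 0.54, against 0.32 over the 6 libraries). Calls gained without that library were therefore not told apart from that trend.

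Transcripts that report on ERK signalling moved in both directions. In the list of 10 ERK output genes, the ERK phosphatase gene DUSP6 fell from 481 ± 55.04 to 78.1 ± 8.45 (SD, n = 3; log2 fold change -2.61, limma adjusted p = 2.8e-05). The signalling inhibitor SPRY4 fell (-0.74), the receptor kinase gene EPHA2 rose (1.30), and 7 did not pass the test. The genes higher and lower were 2 and 4 when adjusted over the list alone, and 2 and 4 over all genes without EV replicate 3, and camera gave an adjusted p of 0.23 for the list. ETV5 stood at -0.51 with an adjusted p of 0.054, and ETV4 (0.09), DUSP4 (3 EV and 11 DUSP5-OE reads, a ratio with an exact binomial counting interval of 1.08 to 22.9), CCND1 (0.56) and MYC (0.48) did not pass either. The kinase gene MAPK3 (-0.10, adjusted p = 0.8) also did not pass. The call on SPRY4 ended without EV replicate 2 (adjusted p = 0.053) and without DUSP5-OE replicates 1, 2 or 3 (0.078, 0.1 and 0.074), while without EV replicate 3 ETV5, CCND1 and MYC passed (adjusted p = 5e-04, 0.0058 and 5.1e-05). ETV5 also passed with edgeR (adjusted p = 0.025), and MAPK3 (-0.41, adjusted p = 0.031), MYC (0.37, 0.021) and ETV5 (-0.52, 0.0052) passed with each library's trend on GC content removed. MAPK3 stood at 0.10 without EV replicate 3 (adjusted p = 0.56), so its direction was not settled.

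Immediate early genes, which are switched on within minutes of a stimulus, moved both ways. Of 26 measured, 8 rose and 3 fell (11 and 5 when adjusted over the list alone, and 13 and 5 over all genes without EV replicate 3). EGR1, FOS (1750 ± 485 to 50.6 ± 11.7) and FOSB (402 ± 72.7 to 36.0 ± 6.59) fell. The stress-induced factor ATF3 rose from 75.8 ± 29.8 to 1965 ± 73.1 (log2 fold change 4.77, limma adjusted p = 5e-06) and the AP-1 component FOSL1 from 1244 ± 276 to 5378 ± 156 (2.13, adjusted p = 5.8e-05). Camera placed the list higher (adjusted p = 0.042), with an adjusted p = 0.53 with an estimated correlation. The call ended without EV replicates 1 or 2 or DUSP5-OE replicates 1 or 3 (adjusted p = 0.063, 0.071, 0.077 and 0.051).

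Among 15 other dual-specificity phosphatases DUSP2 (2.63), DUSP8 (1.72) and DUSP7 (1.09) rose and none fell in limma, edgeR called 3 higher and 0 lower, and 5 had an unadjusted p below 0.05. When adjusted over the list alone 3 rose and 0 fell, and without EV replicate 3 the counts were 6 and 0. By camera the list was higher (adjusted p = 0.04, and adjusted p = 0.31 with an estimated correlation). Of 24 receptor tyrosine kinase and RAS-ERK genes 5 rose, among them the growth factor receptor FGFR1 (0.93), and ERBB2 fell (-1.01). Adjusted over the list alone, 9 rose and 2 fell, and without EV replicate 3 the counts were 11 and 8 (camera adjusted p = 0.042, and adjusted p = 0.29 with an estimated correlation). Camera no longer called the phosphatases without EV replicate 2 or DUSP5-OE replicate 1 (adjusted p = 0.075 and 0.092), or the kinase list without EV replicate 3 or DUSP5-OE replicates 2 or 3 (0.28, 0.063 and 0.095). The call on DUSP7 ended without DUSP5-OE replicate 2 (adjusted p = 0.056) and that on ERBB2 without DUSP5-OE replicate 1 (0.053).

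Among genes of lipid synthesis more fell than rose. Of 21 measured genes of fatty acid synthesis and desaturation 9 fell and 3 rose (10 and 5 when adjusted over the list alone, and 10 and 6 over all genes without EV replicate 3). Beside SCD, the fall took in the desaturase gene FADS2 (8411 ± 631 to 954 ± 141, SD, n = 3; log2 fold change -3.15, limma adjusted p = 2.8e-06), the transcription factor gene SREBF1 (5494 ± 1611 to 1111 ± 56.3; -2.27) and fatty acid synthase, FASN (19754 ± 3527 to 6172 ± 369; -1.66). ACLY, which supplies cytosolic acetyl-CoA, fell by 0.82 on the log2 scale, and the triglyceride-forming enzyme DGAT2 (1.39) was among the genes that rose. Camera placed the list lower (adjusted p = 0.0033), with an adjusted p = 0.081 with an estimated correlation.

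Cholesterol synthesis and uptake showed the same direction in more of its members. Of 24 measured genes 15 fell and none rose in limma (18 and 0 when adjusted over the list alone), and 18 had an unadjusted p below 0.05; edgeR called 17 lower and 0 higher, and without EV replicate 3 19 fell and 2 rose. The sterol reductase gene TM7SF2 (1149 ± 389 to 235 ± 46.8; log2 fold change -2.25), the sterol sensor INSIG1 (1199 ± 193 to 262 ± 19.1; -2.18), DHCR7 (-1.30) and lanosterol synthase, LSS (-1.27), had the largest falls. The call on LSS ended with moderation without trend and robust (adjusted p = 0.053). The camera call (adjusted p = 1.3e-13) held with an estimated correlation (adjusted p = 0.023).

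Ferroptosis genes did not move in 1 direction. Of 27 measured genes of ferroptosis defence 11 rose and 2, SCD and the fatty acid activating enzyme ACSL3 (-0.70, adjusted p = 0.049), fell. Adjusted over the list alone the counts were 12 and 2, and without EV replicate 3 they were 12 and 5. With the replicate block they were 10 and 1. The call on ACSL3 ended under the block (adjusted p = 0.055) and without EV replicates 1 or 2 (0.17 and 0.14) or DUSP5-OE replicates 1, 2 or 3 (0.19, 0.16 and 0.16). The autophagy receptor SQSTM1 rose from 5685 ± 1493 to 23422 ± 814 (SD, n = 3; log2 fold change 2.07, limma adjusted p = 8.9e-05), the ferritin heavy chain FTH1 from 9168 ± 4019 to 33412 ± 1925 (1.95, adjusted p = 0.001), and the ubiquinone reductase AIFM2, known as FSP1, from 459 ± 118 to 1161 ± 30.3 (1.37). GPX4, the glutathione peroxidase that detoxifies lipid peroxides, stood at 3960 ± 1914 in EV and 3339 ± 482 in DUSP5-OE (-0.15, adjusted p = 0.77), and the cystine transporter SLC7A11 at 685 ± 220 and 814 ± 31.9 (0.31, adjusted p = 0.45). By camera the list was higher (adjusted p = 0.0033), with an adjusted p = 0.081 with an estimated correlation. With each library's trend on GC content removed, GPX4 was lower (-0.49, adjusted p = 0.019) and SLC7A11 higher (0.56, adjusted p = 0.0042), but without EV replicate 3 neither passed, with GPX4 at 0.22 (adjusted p = 0.12) and SLC7A11 at 0.01 (0.96), so the direction of GPX4 was not settled.

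Of 30 genes that promote ferroptosis 4 rose and 3 fell (5 and 5 when adjusted over the list alone, and 10 and 6 over all genes without EV replicate 3; camera adjusted p = 0.46). The lipoxygenase ALOXE3 (2.44) and heme oxygenase 1, HMOX1 (2.32), were among those that rose, and SAT1, an enzyme of polyamine breakdown (-1.91), and LPCAT3, which places polyunsaturated fatty acids in phospholipids (-1.22), among those that fell. ACSL4, which activates polyunsaturated fatty acids, was at 3171 ± 1196 and 2144 ± 120 (-0.48, adjusted p = 0.28), and passed the test without EV replicate 3 (-0.85, adjusted p = 9.3e-07). ACSL4 did not pass with each library's trend on GC content removed (-0.28, limma adjusted p = 0.18) or with edgeR (-0.61, adjusted p = 0.15). Targets of the antioxidant regulator NRF2 were raised: 11 of 20 rose, among them HMOX1, OSGIN1 (2.37) and FTH1, and UGDH fell (-0.84), a call that ended without EV replicate 1 (adjusted p = 0.059) or DUSP5-OE replicates 1, 2 or 3 (0.073, 0.077 and 0.079). The counts were 11 and 3 when adjusted over the list alone and 12 and 3 without EV replicate 3, and the camera call (adjusted p = 8e-05) held with an estimated correlation (adjusted p = 0.041). In limma over all genes 8 NRF2 targets were not called, among them NQO1 (0.11, adjusted p = 0.71). FTH1 and other NRF2 targets are also in the ferroptosis defence list, and HMOX1 is in the promotion list. The results of these lists are therefore not separate.

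Interferon response genes rose together. Of 29 measured, 23 rose and none fell in limma (24 and 0 when adjusted over the list alone; 25 had an unadjusted p below 0.05, and edgeR called 23 higher and 0 lower). Beside RSAD2, the oligoadenylate synthetase-like gene OASL rose from 17.97 ± 1.35 to 1532 ± 55.5 (SD, n = 3; log2 fold change 6.38, limma adjusted p = 5.1e-08), CMPK2 from 2.27 ± 3.93 to 112 ± 20.8 and IFI44 from 1.30 ± 2.24 to 90.4 ± 17.5. The CMPK2 log2 fold change of 6.51 was 5.86 without EV replicates 1 or 3 and 7.79 without EV replicate 2, and the IFI44 log2 fold change of 6.44 was 7.49 without EV replicate 2. Genes of NF-kB signalling and inflammatory cytokines moved likewise, with 20 of 27 higher and none lower in limma (22 and 1 when adjusted over the list alone; 24 had an unadjusted p below 0.05, and edgeR called 15 higher and 1 lower). The cytokine gene TNF went from 3 to 111 reads per group (a ratio with an exact binomial counting interval of 13.7 to 202). The chemokine genes CCL20 and CXCL2 had 0 reads in all EV libraries and 26.8 ± 3.77 and 22.6 ± 6.68 in DUSP5-OE, and the apoptosis inhibitor BIRC3 rose from 1247 ± 382 to 12908 ± 277 (3.42). The neutrophil-attracting chemokine gene CXCL8 rose from 3.97 ± 6.07 to 57.9 ± 7.87, a call that ended without DUSP5-OE replicates 1 or 2 (adjusted p = 0.07 and 0.051). The CXCL8 log2 fold change of 4.84 was 6.09 without EV replicate 1 and 3.83 without EV replicate 2. The camera calls of the interferon list (adjusted p = 8.4e-25) and of the NF-kB list (1.6e-16) held with an estimated correlation (adjusted p = 0.0083 and 0.041).

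**Figure D2:**
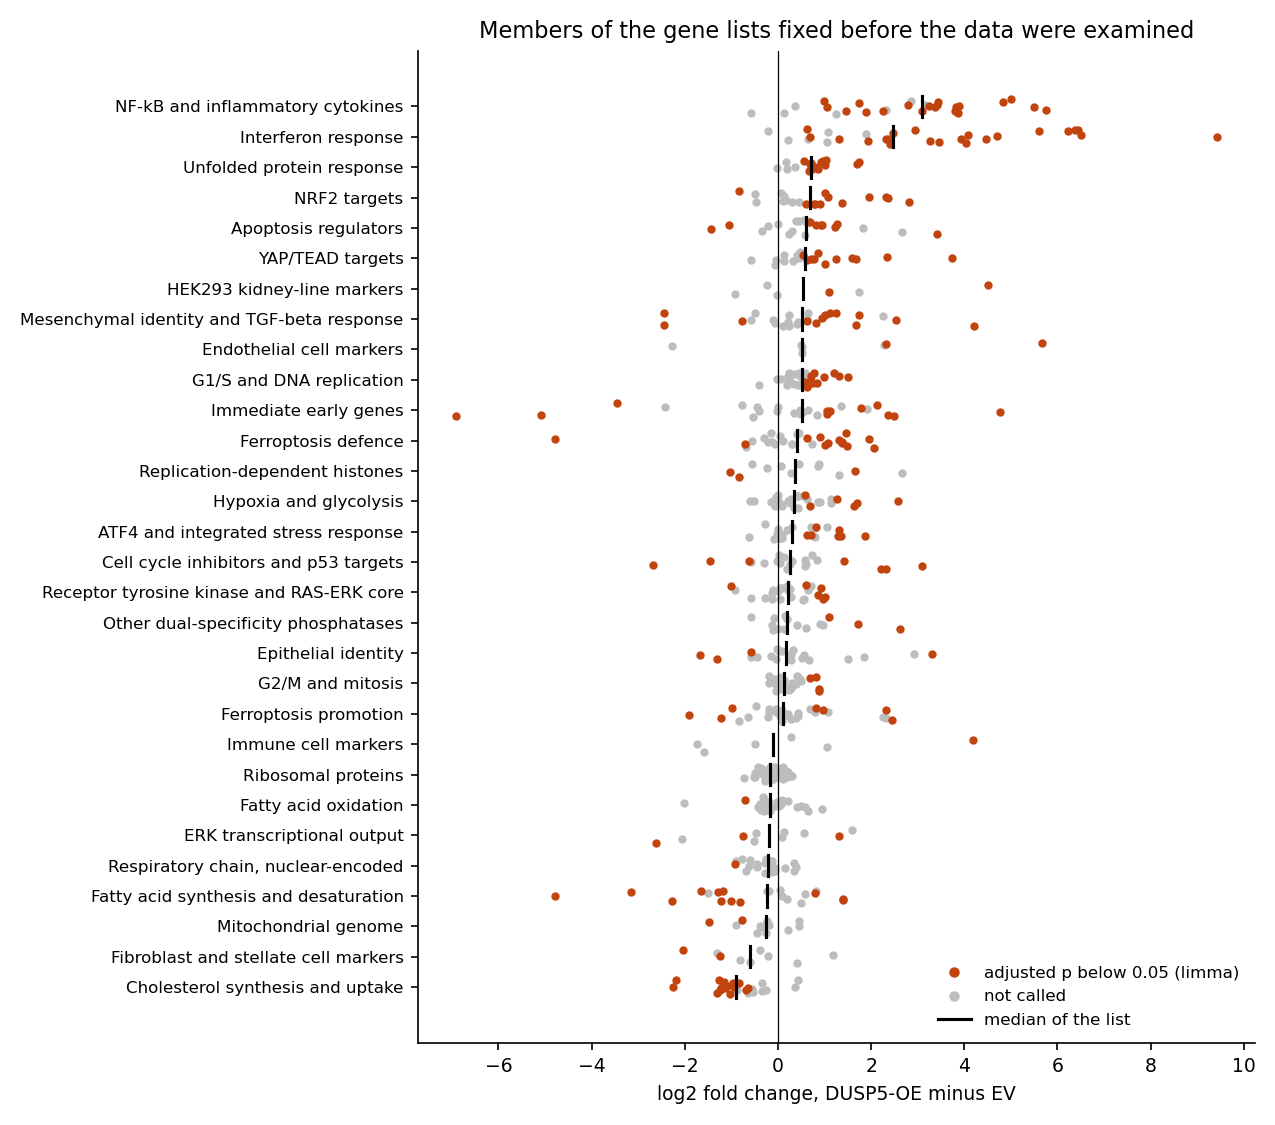
Log2 fold change (DUSP5-OE minus EV, log2(value + 0.5) scale) of each tested member of 30 gene lists, coloured where limma's adjusted p was below 0.05, with a bar at each list's median. The interferon and NF-kB lists lie to the right with 23 and 20 members higher, and the cholesterol list lies to the left with 15 members lower.

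Genes of protein folding stress rose as well. Of 18 unfolded protein response genes 13 rose and none fell in limma (14 and 0 when adjusted over the list alone; 14 had an unadjusted p below 0.05, and edgeR called 11 higher and 0 lower). They included the endoplasmic reticulum chaperone HYOU1 (5140 ± 586 to 10473 ± 683, SD, n = 3; log2 fold change 1.03, limma adjusted p = 0.0016) and the disulfide isomerase PDIA4 (4423 ± 394 to 8933 ± 316). The camera call (adjusted p = 2.2e-08) held with an estimated correlation (adjusted p = 0.023). Of 23 genes of the ATF4 and integrated stress response 7 rose and none fell in limma (9 and 0 when adjusted over the list alone; 11 had an unadjusted p below 0.05, and edgeR called 6 higher and 0 lower), with TRIB3 (1.87), PPP1R15A (1.35), STC2 (1.32) and the amino acid transporter SLC7A5 (1.29) at the top. Of 31 hypoxia and glycolysis genes 6 rose and none fell in limma (7 and 0 when adjusted over the list alone; 12 had an unadjusted p below 0.05, and edgeR called 6 higher and 0 lower), led by hexokinase 2, HK2 (187 ± 26.7 to 1108 ± 142; 2.57), and the glucose transporter SLC2A1 (1.70). Camera placed both lists higher (adjusted p = 0.0012 and 0.0016), with adjusted p = 0.22 and 0.31 with an estimated correlation. Without EV replicate 3 the counts were 12 and 0 for the ATF4 list and 16 and 1 for the hypoxia list.

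Genes of DNA replication were raised as a list. Of 29 G1/S genes 12 rose and none fell in limma (18 and 0 when adjusted over the list alone; 18 had an unadjusted p below 0.05, and edgeR called 9 higher and 0 lower). The licensing factor CDT1 rose from 360 ± 101 to 998 ± 37.6 (SD, n = 3; limma adjusted p = 0.0012), cyclin E1, CCNE1, by 1.32, E2F2 by 1.21 and the ribonucleotide reductase subunit RRM2 by 0.98 on the log2 scale. Without EV replicate 3 20 rose and 1 fell, and the camera call (adjusted p = 2.7e-08) held with an estimated correlation (adjusted p = 0.023). Of 30 G2/M genes 4 rose and none fell in limma (4 and 0 when adjusted over the list alone; 6 had an unadjusted p below 0.05, and edgeR called 4 higher and 0 lower), among them the mitotic kinase PLK1 (0.88). Camera placed that list higher (adjusted p = 0.019), with an adjusted p = 0.49 with an estimated correlation, and the call ended without EV replicate 3 (adjusted p = 0.7), where 8 rose and 7 fell. With each library's trend on GC content removed, camera placed the G2/M list higher (adjusted p = 0.00011), and 8 rose and none fell. Of 21 cell cycle inhibitors and p53 targets 4 rose, including FAS (3.09) and GADD45A (2.33), and 3 fell, including TP53INP1 (-2.68). When adjusted over the list alone 5 rose and 3 fell, and without EV replicate 3 10 and 5 did (camera adjusted p = 0.14). Among 22 apoptosis regulators 7 rose and 2 fell (10 and 2 when adjusted over the list alone, and 14 and 3 over all genes without EV replicate 3). BIRC3 and BIRC2 (1.22), which inhibit apoptosis, rose with the pro-apoptotic PMAIP1 (1.27), and the pro-apoptotic BMF (-1.43) fell. Camera placed the list higher (adjusted p = 0.0022), with an adjusted p = 0.084 with an estimated correlation, and the call on BIRC2 ended without DUSP5-OE replicate 1 (adjusted p = 0.053).

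Targets of the transcriptional regulators YAP and TEAD were raised, with 11 of 20 higher and none lower in limma (13 and 0 when adjusted over the list alone; 14 had an unadjusted p below 0.05, and edgeR called 8 higher and 0 lower). Without EV replicate 3 14 rose and 2 fell. ANKRD1 rose from 93.7 ± 12.3 to 1244 ± 31.8 (SD, n = 3; log2 fold change 3.73, limma adjusted p = 1.2e-06), NUAK2 by 2.35 and AJUBA by 1.58, and the camera call (adjusted p = 7.6e-08) held with an estimated correlation (adjusted p = 0.041). Of 26 genes of mesenchymal identity and TGF-beta response 10 rose and 3 fell (10 and 3 when adjusted over the list alone, and 11 and 5 over all genes without EV replicate 3). The transcription factor SNAI2 (1.60 ± 1.14 to 34.7 ± 1.42; 4.20) and the urokinase receptor PLAUR (2.54) rose, while the matrix genes TNC (-2.45) and SPARC (-2.44) fell. By camera the list was higher (adjusted p = 0.013), with an adjusted p = 0.098 with an estimated correlation and an adjusted p = 0.053 without EV replicate 3.

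Of 20 epithelial genes 1 rose, OVOL2 (3 EV and 35 DUSP5-OE reads, a ratio with an exact binomial counting interval of 3.93 to 63.3), and the tight junction genes TJP3 (-1.67) and CLDN7 (-1.31) and the keratin gene KRT18 (-0.58) fell. Adjusted over the list alone 6 rose and 4 fell, without EV replicate 3 7 and 5 did, and edgeR, which left OVOL2 untested, called 0 higher and 4 lower (camera adjusted p = 0.73). The OVOL2 log2 fold change of 3.30 was 2.66 without EV replicate 1 and 4.26 with a pseudocount of 0.1 (adjusted p = 0.06). The limma calls on OVOL2, CLDN7 and KRT18 ended without EV replicate 1 (adjusted p = 0.054, 0.065 and 0.087) and without DUSP5-OE replicates 1 (0.14, 0.16 and 0.11), 2 (0.082, 0.14 and 0.14) or 3 (0.13, 0.13 and 0.083). That on TJP3 ended without DUSP5-OE replicates 1 or 2 (adjusted p = 0.07 in both).

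Genes of energy metabolism and of the ribosome had few calls. Of 25 fatty acid oxidation genes HADH, a dehydrogenase of that pathway, fell (413 ± 27.3 to 255 ± 18.3, SD, n = 3; log2 fold change -0.70, limma adjusted p = 0.024) and none rose in limma. Adjusted over the list alone 0 rose and 1 fell, edgeR called 0 higher and 1 lower, 7 had an unadjusted p below 0.05, and without EV replicate 3 6 rose and 7 fell (camera adjusted p = 0.23). The call on HADH ended without EV replicates 1 or 2 (adjusted p = 0.093 and 0.054) or DUSP5-OE replicates 1, 2 or 3 (0.11, 0.096 and 0.12). In those fits the log2 fold change of HADH stayed between -0.75 and -0.64. The rate-controlling transferase CPT1A stood at 0.41 (adjusted p = 0.14, and 0.023 without EV replicate 3).

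Of 26 nuclear-encoded respiratory chain genes UQCRB fell (-0.92) and none rose in limma, and edgeR called 1 lower and 0 higher. When adjusted over the list alone 0 rose and 1 fell, and 2 had an unadjusted p below 0.05. Of 13 genes of the mitochondrial genome MT-ATP8 (-1.49) and MT-ND3 (-0.78) fell and none rose in limma. Adjusted over the list alone 0 rose and 2 fell, 3 had an unadjusted p below 0.05, and edgeR called 3 lower and 0 higher. None of 47 ribosomal protein genes was called by limma, over all genes or adjusted over the list alone, although 4 had an unadjusted p below 0.05 and edgeR called 2 lower. RPS16, the most abundant of them, stood at 100840 ± 52307 in EV and 78319 ± 9504 in DUSP5-OE (adjusted p = 0.61). In EV replicate 3 the median members of the respiratory chain, mitochondrial and ribosomal lists lay 0.83, -1.04 and 0.84 (log2) from the other EV libraries. Camera placed the respiratory chain and ribosomal lists lower (adjusted p = 0.028 and 0.019), with adjusted p = 0.66 and 0.72 with an estimated correlation, and gave an adjusted p of 0.06 for the mitochondrial genome. Without EV replicate 3 the respiratory chain had an adjusted p of 0.94 (5 genes higher, 3 lower), the ribosomal list turned to higher (0.23, with 13 higher and 5 lower) and the mitochondrial genome was lower (0.00028, with 0 higher and 7 lower). Without DUSP5-OE replicates 2 and 3 the respiratory chain had adjusted p-values of 0.078 and 0.11 and the mitochondrial genome 0.033 and 0.04, and the ribosomal list had 0.16 without DUSP5-OE replicate 3. The call on UQCRB ended without DUSP5-OE replicates 2 or 3 (adjusted p = 0.099 and 0.12). The call on MT-ND3 ended without EV replicates 2 or 3 (0.1 and 0.098) or DUSP5-OE replicates 1, 2 or 3 (0.14, 0.057 and 0.17), and both calls ended with the GC trend removed (UQCRB 0.16, MT-ND3 0.062). Moderation without trend and robust ended the calls on UQCRB, MT-ND3 and MT-ATP8 (0.11, 0.14 and 0.055).

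Of 12 replication-dependent histone genes H3C4 rose (1.66) and H2BC21 (-1.04) and H2AC6 (-0.83) fell. The counts were 2 and 2 when adjusted over the list alone and 4 and 2 without EV replicate 3 (camera adjusted p = 0.88). Histone genes resemble one another, so their reads are uncertain. The libraries were made from poly(A) RNA, so histone transcripts without a poly(A) tail are poorly covered. The calls on H3C4 and H2BC21 ended without EV replicate 1 (adjusted p = 0.067 and 0.08) and DUSP5-OE replicates 1 (0.12 and 0.073), 2 (0.093 and 0.12) or 3 (0.08 and 0.09), that on H3C4 also without EV replicate 2 (0.051), and that on H2AC6 without DUSP5-OE replicates 2 or 3 (0.078 and 0.069).

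Of 6 tested immune markers ITGAM, an integrin of myeloid cells, rose from 7.28 ± 0.77 to 141 ± 8.36 (SD, n = 3; log2 fold change 4.19, limma adjusted p = 2.3e-05). The others did not pass in limma over all genes. In limma adjusted over the list alone, in edgeR and with the GC trend removed 1 was higher and 1 lower, and the list's median (-0.11) lay below 0 while its mean (0.28) lay above it (camera adjusted p = 0.73). The leukocyte genes PTPRC and LYZ had 0 reads in the 3 DUSP5-OE libraries, which allows up to 3 reads each over the group. Of 9 fibroblast and stellate cell markers the collagen genes COL1A1 (849 ± 90.2 to 207 ± 26.2; -2.04) and COL3A1 (-1.25) fell and none rose in limma. When adjusted over the list alone 0 rose and 2 fell, edgeR called 0 higher and 2 lower, and 4 had an unadjusted p below 0.05. Camera placed the list lower (adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). Of 7 endothelial markers ROBO4 (0 EV reads, 24.7 ± 0.42 in DUSP5-OE) and ESAM (2.31) rose and none fell in limma. Adjusted over the list alone 3 rose and 0 fell, 4 had an unadjusted p below 0.05, and edgeR called 2 higher and 0 lower. By camera the list was higher (adjusted p = 0.02, and adjusted p = 0.14 with an estimated correlation). Without EV replicate 3 the fibroblast list had an adjusted p of 0.095 (0 higher, 3 lower) and the endothelial list 0.11 (3 higher, 0 lower), and the endothelial list had 0.063 without DUSP5-OE replicate 2. The call on COL3A1 ended without DUSP5-OE replicates 1, 2 or 3 (adjusted p = 0.076, 0.065 and 0.098).

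Of 6 markers of HEK293, a kidney-derived line, HOXD10 (4.52) and PHF21B (1.10) rose and none fell in limma, edgeR called 2 higher and 0 lower, and 2 had an unadjusted p below 0.05. The counts were 2 and 0 when adjusted over the list alone (camera adjusted p = 0.36). The abundant members HOXC10 (2127 ± 112 to 1796 ± 45.3, SD, n = 3; adjusted p = 0.31) and PAX2 (1202 ± 164 to 1191 ± 20.7; 0.99) did not pass, though HOXC10 did with the GC trend removed (-0.34, adjusted p = 0.044). The call on HOXD10 ended without DUSP5-OE replicates 1, 2 or 3 (adjusted p = 0.063, 0.067 and 0.059), and its value was 5.56 without EV replicate 3. The call on PHF21B ended without EV replicates 1 or 2 (0.07 and 0.064) or DUSP5-OE replicates 1, 2 or 3 (0.055, 0.15 and 0.13). Of the acinar and endocrine pancreas markers 2 were tested and neither passed in limma, over all genes or adjusted over the list alone, and edgeR called 0, although 1 had an unadjusted p below 0.05. CTRB2, a digestive enzyme precursor, had 1 EV and 10 DUSP5-OE reads (adjusted p = 0.16).

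EV replicate 3 differed from the other EV libraries across the transcriptome. Its chi-square per degree of freedom over genes was 94.8 against EV replicate 1 and 112 against EV replicate 2, where EV replicates 1 and 2 gave 7.80 and the pairs of DUSP5-OE libraries 3.17 to 11.99. Ribosomal protein transcripts took 5.70% of its reads, against 3.01% and 3.03% in the other EV libraries and 2.81 to 3.63% in DUSP5-OE, and mitochondrial transcripts took 3.48%, against 6.13% and 7.61% in EV and 3.93 to 5.13% in DUSP5-OE. Across 11500 genes with a mean of at least 50, which are not independent replicates, its deviation from the other EV libraries followed transcript GC content (Spearman's rho 0.78). The difference between the groups carried a GC trend of rho 0.32 over the 6 libraries and 0.54 without EV replicate 3.

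**Figure D3:**
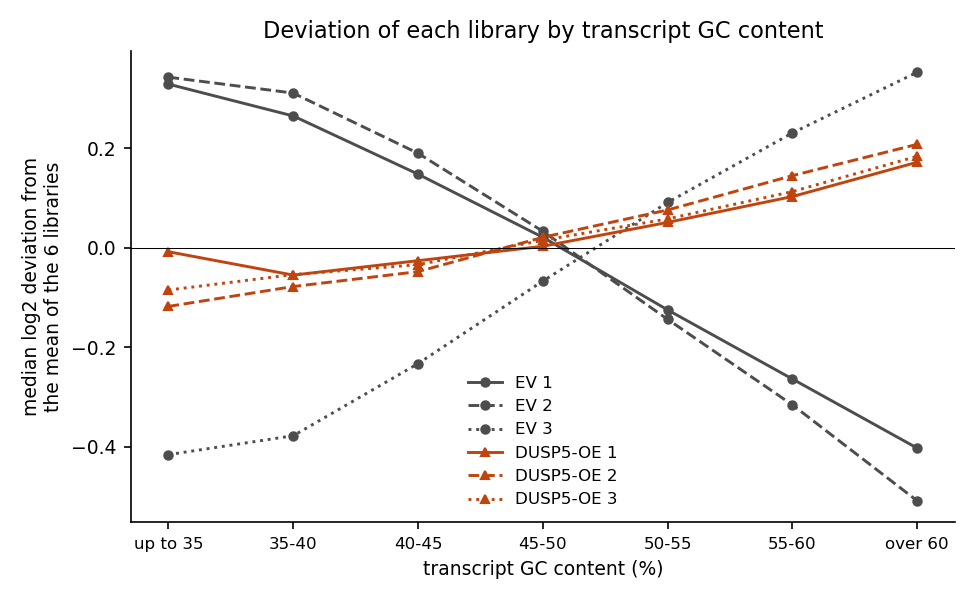
Median log2 deviation of each library from the mean of the 6 libraries, in bins of transcript GC content (%), for 11500 genes with a mean of at least 50. EV replicate 3 runs from -0.416 in the lowest bin to 0.353 in the highest, EV replicates 1 and 2 run the other way, and the DUSP5-OE libraries lie between them.

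**Figure D4:**
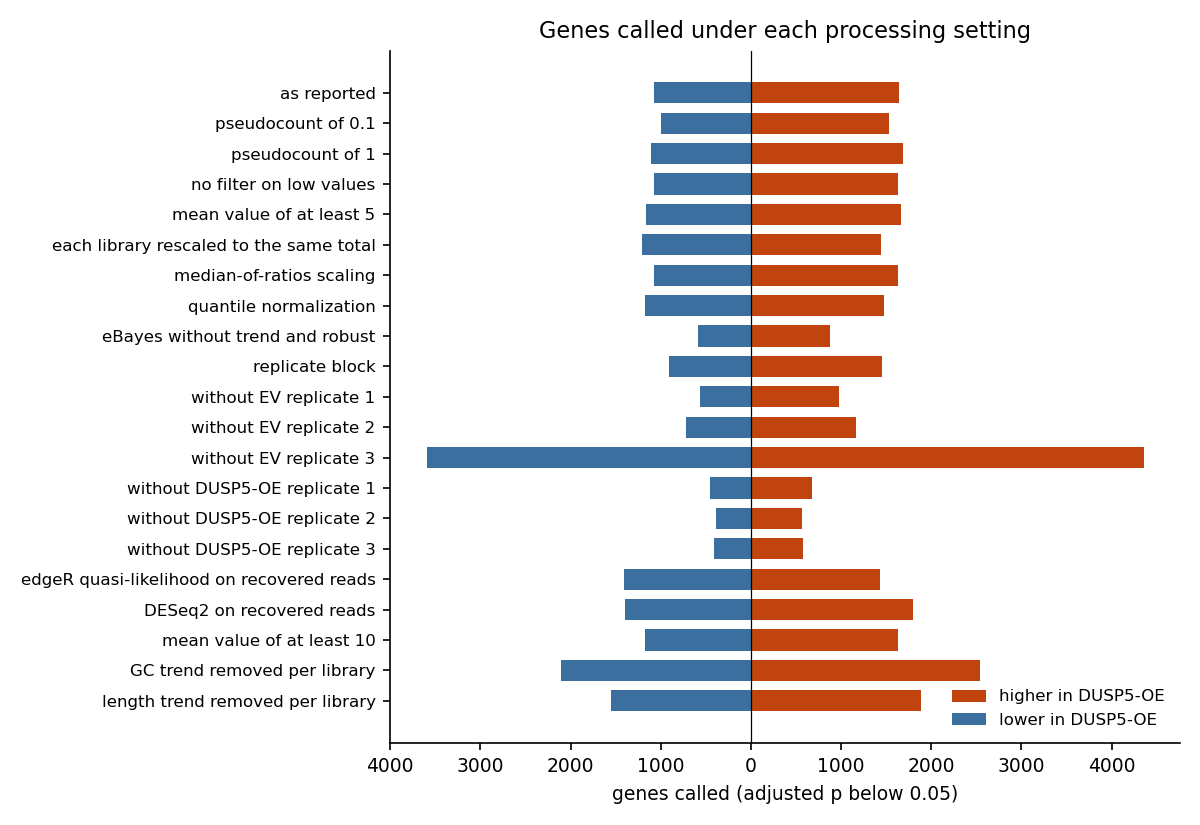
Number of genes called higher (right) and lower (left) in DUSP5-OE under each processing setting, at an adjusted p below 0.05. The reported counts are 1638 and 1076, and the highest are 4358 and 3591 without EV replicate 3.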

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

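The edgeR, DESeq2, mean of at least 10, GC and length settings were chosen after seeing the data. DUSP5 and SCD kept their calls under all 20 alternatives, with log2 fold changes of 6.80 to 7.07 and -4.97 to -4.68. Of the 124 genes named by rule 83 kept their call under every alternative that tested them, and no called one turned to the opposite call. Of the 30 lists, run under 12 alternatives, 13 kept theirs. Moderation without trend and robust ended the calls of 27 named genes. Median-of-ratios scaling differed from the deposited scaling by the common factor 1.012, so it tests nothing.

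Genes higher and lower numbered 875 and 590 with moderation without trend and robust, and 2546 and 2109 with the GC trend removed; the cause was not tested. Leaving out 1 library gave 571 to 4358 genes higher and 392 to 3591 lower, and 516 to 1703 and 366 to 1030 by at least 2-fold. The lowest came without DUSP5-OE replicate 2 and the highest without EV replicate 3, where 1637 of the 1638 higher and 1060 of the 1076 lower genes kept their call. A fit with fewer libraries is a weaker test. A call that ended without 1 library therefore does not by itself show that this library carried it. With each library rescaled to an equal total 1438 were higher and 1212 lower, and with edgeR 1433 and 1408.

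With the replicate block 1458 genes were higher and 906 lower. Correlations of same-numbered libraries were -0.205, 0.053 and -0.289, and those of differently numbered libraries ran from -0.214 to 0.273. They gave no sign that the numbers pair the libraries. Under the block the kinase list (adjusted p = 0.064), KRT18 (0.059), HADH (0.061) and ACSL3 (0.055), named outside the rule, lost their calls and the mitochondrial genome gained one (0.043).

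With an estimated correlation camera lost 14 list calls, among them immediate early genes (adjusted p = 0.53), fatty acid synthesis (0.081), ferroptosis defence (0.081) and G2/M (0.49). The estimated correlations of immediate early genes and G2/M (0.228 and 0.222) lay above the preset 0.01. Those of fatty acid synthesis and ferroptosis defence (-0.021 and -0.001) lay below it, so a higher correlation did not end those calls. With an estimated correlation camera also uses the 4 residual degrees of freedom, and with the preset far more. The interferon list went from an adjusted p of 8.4e-25 to 0.0083 although its estimated correlation was -0.019. A higher adjusted p under this setting is therefore not by itself a sign of correlated genes. Fry gave an adjusted p of 0.0014 for ERK output, 0.16 for immediate early genes and 0.25 for G2/M. It asks whether a list's genes change, and camera whether they change more than other genes. The values of fry therefore do not replace those of camera. With the GC trend removed immediate early genes had 0.17, and the other phosphatases (0.094), the kinase list (0.094) and the endothelial markers (0.089) also lost their calls. Leaving out 1 library gave 0.016 to 0.077 for immediate early genes, 0.0029 to 0.7 for G2/M and 0.00012 to 0.23 for ribosomal proteins, whose direction reversed without EV replicate 3 (0.23); the cause was not tested. At 15215332 reads in the shallowest library a gene near 3 reads per group has too few for a firm ratio.

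The groups as labelled gave 1638 and 1076 genes, and the highest of the other splits of the 6 libraries gave 0 in either direction. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.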

Other observations

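The tests of the GC, length and labelling explanations for EV replicate 3, of immune cells, and of the sterol and SREBP explanations for SCD, and the 4 gene lists of the next paragraph, were chosen after the results were seen.

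Antigen presentation genes rose with the interferon list. Of 15 measured 14 were higher in DUSP5-OE by limma, among them the class I genes HLA-B (113 ± 13.0 to 1019 ± 121, SD, n = 3; log2 fold change 3.16, adjusted p = 4.9e-06) and HLA-C (2.17), the peptide transporter TAP1 (642 ± 147 to 4075 ± 212; 2.69) and the immunoproteasome subunit PSMB9 (2.72). HLA genes resemble one another, so their reads are uncertain. Of 12 receptors and adaptors of the TNF superfamily 6 rose, including TNFRSF1B (116 ± 22.0 to 1933 ± 128; 4.07), TNFRSF9 (5.49) and TRAF1 (2.97). The TNFRSF9 log2 fold change was 4.51 without EV replicate 1 and 6.07 without EV replicate 3. Of 11 laminin genes 3 rose and 1 fell. LAMB3 (13.6 ± 1.74 to 448 ± 20.6; 5.00), which encodes a laminin chain of epithelial basement membranes, was among those that rose, and LAMA4 fell (-1.90). Of 11 endoderm and foregut transcription factors 3 rose and 1 fell: GATA6 (35.9 ± 9.75 to 271 ± 16.0; 2.94) and ONECUT2 (2.12) rose, and FOXA1 fell from 353 ± 35.5 to 26.5 ± 3.90 (-3.72, adjusted p = 8.7e-06). Without EV replicate 3 the genes higher and lower were 15 and 0 for antigen presentation, 9 and 0 for the TNF superfamily, 6 and 2 for laminins and 7 and 2 for the foregut factors.

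Interferon and NF-kB genes rose in DUSP5-OE, with 43 of 56 called higher. All 43 were still called higher without EV replicate 3, and 43 with each library's GC trend removed, which argues against either as the whole cause. Leukocytes among the DUSP5-OE cells were tested in 2 ways: the first asked whether immune markers reached 100 units, and it came out in favour through 1 gene, ITGAM, at 141.3 (7.3 in EV). Because ITGAM is a single gene, a second test was added after that outcome and with its own values already known, so it is weaker evidence: 1 of 6 tested immune markers was higher, PTPRC and LYZ had 0 reads in DUSP5-OE, and CD14 stood at 34.7 in EV and 12.3 in DUSP5-OE, which argues against leukocytes. The EV cells carry a vector too, so a response to the vector alone would be in both groups, but one to expressing any introduced transcript or protein stays open, since 0 groups overexpressed another or an inactive protein, and so does an effect of DUSP5 itself.

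SCD fell further than the sterol genes. Its log2 fold change lay -2.53 ± 0.30 (SE) from that of TM7SF2, the lowest member of the cholesterol list. FADS2, of the fatty acid list, also fell further than TM7SF2 (-3.15 against -2.25). Genes with a shared cause can fall by different amounts. This therefore does not decide whether a general fall of sterol-regulated genes was the whole cause. The log2 fold change of SCD was -4.75 with the GC trend removed, which argues against that trend. Lower SREBP output may be part of the fall: 15 of the 24 measured cholesterol genes were lower, none was higher, and SREBF1 itself fell. Whether ERK signalling takes part was not tested, because no group here altered it apart from DUSP5.

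EV replicate 3 and EV replicates 1 and 2 may differ in how their libraries were made. A smooth trend on GC content took 56.8% of the variance of EV replicate 3's deviation from the other EV libraries. Transcript length took 23.2%, which decides nothing. Against the mean of the 6 libraries, the median deviation (log2) of EV replicate 1 ran from 0.329 in the lowest GC bin to -0.403 in the highest. That of EV replicate 2 ran from 0.343 to -0.509 and that of EV replicate 3 from -0.416 to 0.353. Which of them carries the trend was therefore not settled. The DUSP5 value of EV replicate 3 lay 106.6 times below the lowest DUSP5-OE library, which argues against a swapped group label. Cells of another type cannot be told apart from a difference in library making, since the highest median deviation over the marker lists, 0.82 (log2) for immune markers, lay between the values set for and against them. That value rests on 6 tested genes. The respiratory chain and ribosomal lists, which mark no cell type, lay at 0.83 and 0.84, so it decides nothing. A difference between the cultures stays open and was not tested.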
